A study of Mus musculus with 25 samples.

How the data were processed

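RNA sequencing of mouse liver was analysed in 25 libraries, each from a separate mouse according to the sample titles. The labels place 5 libraries in the Untreated group, 6 in DEN (diethylnitrosamine, an alkylating liver carcinogen), 5 in DEN_CAF (carcinogen, then caffeine), 4 in DEN_SOR (carcinogen, then sorafenib) and 5 in DEN_CAF_SOR (carcinogen, then both drugs). Per the labels' protocols, RNA was isolated with a phenol-based lysis reagent and silica columns and libraries were made with a SMARTer kit. Read alignment used HISAT2 2.0.5, gene counting used featureCounts 1.5.0-p3 and the genome build was GRCm39, per the submitters' processing notes. The annotation release and whether counting used strand are not given in the sources used here, so overlapping and antisense genes are uncertain.

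The deposited tables, 1 per group, are named for FPKM but hold another unit. Each deposited column is a signal made of whole reads per gene divided by 1 size factor per library, without division by gene length. In every library 100% of the values were whole multiples of 1 step within a tolerance of 0.01 read, so the read counts behind the deposited values were recovered. The authors' size factors equalled median-of-ratios factors, within 0.0%, only when computed over pairs of groups: Untreated with DEN_CAF, and each other group with DEN or, for DEN itself, with DEN_CAF. The tables were therefore normalised separately, and going back to reads made the 5 tables comparable. The design had assumed FPKM, so FPKM was computed here from the recovered reads, the library total and the gene length that the tables list. The design named edgeR for files with raw counts. The files hold none as such, so limma on FPKM stayed the test by which genes are called, and edgeR and DESeq2 on the recovered reads are given beside it.

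Assigned reads per library are given in the results. At that depth, libraries of the same group differed by more than the counting of reads alone gives. For the named genes these sources of error were not separated. Among the 51 pairs of libraries from the same group, chi-square per degree of freedom on reads ran from 21.9 to 491, so no library was a repeat of another. The tables listed 30524 genes, of which 24774 stood in all 5. Genes missing from a table had been dropped there when the group and its partner held at most 1 read, so they were left out of the test, and counted as 0 in a later setting.

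Genes with an FPKM of 1 or more in at least 4 libraries were tested (12741 genes). The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with 1 coefficient per group in a single fit of all 25 libraries (20 residual degrees of freedom), eBayes with a trend, and Benjamini-Hochberg adjustment within each of 7 comparisons at 0.05, two-sided. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Errors are standard errors (SE) of log2 fold changes from this fit, or standard deviations (SD) of FPKM between mice. An adjusted p without another tool's name is from limma. Groups of genes were tested with camera of limma (preset inter-gene correlation of 0.01, adjusted over 43 lists), and again with a correlation estimated per list. The 47 gene lists cover hepatocyte functions and zones, sex-biased liver genes, stress and damage responses, tumour markers, drug targets and markers of other cell types that a piece of liver can hold. They hold 900 genes, of which 687 were tested, and 43 lists had the 5 or more tested members needed. Some genes stand in more than 1 list. For mean list scores, exact permutation tests over all regroupings of the libraries were run, two-sided, with adjustment over the 45 tests of that kind.

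On reads simulated with the mean, spread and library sizes of the real reads (12388 genes), the limma step recovered 8.96% of 1.5-fold, 35.8% of 2-fold and 83.3% of 4-fold changes for DEN against Untreated. For 2-fold changes the share was 46.3% for DEN_CAF against DEN, 37.3% for DEN_SOR against DEN and 50.75% for DEN_CAF_SOR against DEN. It was 40.3% for DEN_CAF_SOR against DEN_SOR and 44.8% for DEN_CAF_SOR against DEN_CAF. A simulated list shifted 1.5-fold as a whole was called in each of these comparisons. Genes were drawn independently of each other there, so this does not show how the list test behaves on the correlated genes of real mice.

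The groups, tests, gene lists and the rule for named genes were fixed before the data were examined. The rule takes, per comparison, the 8 called genes with the largest and the 8 with the smallest log2 fold change. These had to be protein-coding with a mean FPKM of 1 or more in an arm, a symbol that is not a clone name, and every library of the first arm on the same side of the other arm's mean. With fewer than 6 calls all were taken, and with 0 calls the 3 genes with the smallest unadjusted p in each direction, given as not called. It adds the 3 called members with the largest change of each list past the camera test or with 25% or more of its members called, and a preset group that includes Afp, Gpc3, Glul, Mki67, Cdkn1a, Cyp1a1, Cyp1a2, Cyp3a11, Adora1, Adora2a, Adora2b, Kdr, Pdgfrb and Braf. Beyond the rule, members named as examples of a list with 0 called members are among the 3 with the smallest unadjusted p. This was added after the data were seen. Tests that share the DEN libraries were compared with 100 simulated sets of unchanged groups and with 10 splits of the DEN libraries.

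Other settings fixed beforehand were a pseudocount of 0.1, no filter, median-ratio and TPM scaling, fits of the compared groups alone, robust eBayes, library weights, the replicate number as a block, an estimated correlation and leaving out each library. Added after the data were seen were edgeR 4.0.16 (quasi-likelihood, 17159 genes) and DESeq2 1.42.0 on recovered reads, fits without libraries that carried Xist reads or over 20% mitochondrial reads, fits with covariates for the mitochondrial share, for Dbp minus Arntl or for libraries numbered 3 and 4, and fits within each set of numbers. Each list past the test was also tested on leaving out each library. The largest median fold change of all genes under a scaling was 0.05 in size (log2). Coordinates are those the tables list for GRCm39. A second annotation, on build GRCm38, served for the GC content of genes matched by identifier (97.4% of the tested genes). Members of the Mup, Cyp2c, Cyp2a, Cyp2b, Gsta, Ifi27l2, Oas1 and Sult families, and pseudogenes, share reads with close copies and are uncertain as single genes.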

Results

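According to the labels, the mice were 5-week-old C3H/HeJ males, a strain prone to liver cancer, and diethylnitrosamine was injected at 25 mg/kg in 5 cycles. Saline served for the Untreated group. After a month of rest, caffeine at 50 mg/kg 3 times a week, sorafenib at 30 mg/kg 2 times a week, both, or their vehicles were given by gavage for 3 weeks. Liver RNA was sequenced from 25 mice: 5 Untreated, 6 DEN, 5 DEN_CAF, 4 DEN_SOR and 5 DEN_CAF_SOR. Assigned reads ran from 15723658 to 19309618 in Untreated, 15821764 to 19925372 in DEN and 17070231 to 19859763 in DEN_CAF. They ran from 14750278 to 20107029 in DEN_SOR and 17978389 to 21992613 in DEN_CAF_SOR.

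Xist, the RNA of the inactive X chromosome that marks female cells, had 22879, 29770 and 13370 reads in Untreated libraries 3, 4 and 5. It had at most 21 reads in each of the 20 carcinogen-treated libraries. The Y-linked gene Ddx3y had 84, 30 and 48 reads in those 3 Untreated libraries, against 1028 and 1373 in Untreated 1 and 2. Thus 3 of 5 Untreated livers carry the expression of female animals although the labels say male, and the genes of the DEN comparison are also counted without them. Genes of the mitochondrial chromosome, which make the respiratory chain, took 34.8% of the reads in DEN_SOR 4, 33.4% in DEN 3, and 23.6% and 23.1% in DEN_CAF 3 and 4. They averaged 19.2% with an SD of 9.51% in the 10 libraries numbered 3 and 4, against 7.46% with an SD of 0.967% in the other 15. Of these 10, Untreated 4 (6.36%) and DEN 4 (9.58%) lay no higher than the top of the others (9.81%), and libraries numbered 3 ran from 13.5% to 33.4%.

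**Figure D1:**
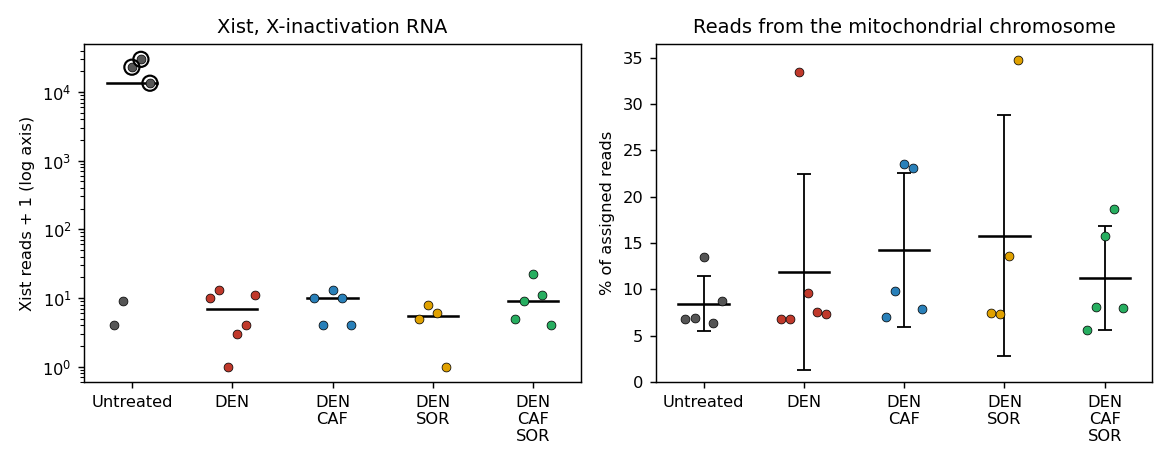
Xist reads per library (reads + 1; bars are medians, rings mark the 3 Untreated libraries with 22879, 29770 and 13370 reads) and the percentage of reads from mitochondrial genes (mean and SD per group), with DEN 3 at 33.4%.

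DEN against Untreated showed rises of single fetal and damage genes. H19, an imprinted growth RNA silent in adult liver, rose from 0.377 ± 0.372 FPKM (n = 5) to 226 ± 448 (n = 6), a log2 fold change of 4.78 (SE 0.95, adjusted p = 0.00873). Cdkn1a, the cell-cycle inhibitor driven by p53, rose from 1.19 ± 0.468 to 22.4 ± 33.0 FPKM (2.73, SE 0.51, adjusted p = 0.00531), and Phlda3, a further p53 target, from 0.645 ± 0.320 to 4.43 ± 2.20 (1.65, SE 0.24, adjusted p = 0.000433). Glul, the glutamine synthetase of hepatocytes around the central vein, fell from 146 ± 31.6 to 52.4 ± 26 FPKM (-1.71, SE 0.39, adjusted p = 0.0200). Nr1d1, a repressor of the daily clock, fell from 42.2 ± 14.9 to 7.66 ± 4.67 FPKM (-2.41, SE 0.41, adjusted p = 0.00215). The DEN mean of H19 was 45.0 FPKM without DEN 4 and that of Cdkn1a 8.99 without DEN 1, and both genes stayed called. Without the Untreated libraries with Xist reads the limma calls of H19, Cdkn1a and Glul were lost, while those of Phlda3 and Nr1d1 held. On GRCm39 these genes are H19 (ENSMUSG00000000031, chr7 142129262-142131886), Cdkn1a (ENSMUSG00000023067, chr17 29309950-29319701), Glul (ENSMUSG00000026473, chr1 153775690-153785469) and Nr1d1 (ENSMUSG00000020889, chr11 98658758-98666159).

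Among the largest rises were Cib3 (2.21 ± 1.42 to 24.2 ± 18.4 FPKM, log2 2.89, SE 0.49), Tspan8 (0.617 ± 0.450 to 24.9 ± 42.8, log2 2.73, SE 0.66) and Gsta1, a glutathione transferase (2.29 ± 2.97 to 14.8 ± 8.94, log2 2.48, SE 0.53). The DEN mean of Tspan8 was 7.65 without DEN 4, and its call was lost without any 1 of the Untreated libraries or DEN 3. S100a11 (log2 2.43, SE 0.53), Cd63 (2.33, SE 0.55), the interferon-induced Ifi27l2b (2.25, SE 0.46) and the lipase gene Lpl (2.07, SE 0.39) rose too. The largest falls were in Mup9, a urinary protein of males (545 ± 751 to 8.88 ± 8.68 FPKM, log2 -4.68, SE 1.13), Cyp2c69 (-3.81, SE 0.99), Sult3a1 (-3.72, SE 0.91) and Mup18 (-3.62, SE 0.81). They were followed by Cyp2c40 (-3.36, SE 0.88), Cyp46a1 (-2.70, SE 0.69) and Cyp2g1 (-2.15, SE 0.39). Without the 3 Xist libraries the fold changes of Cyp2c69, Sult3a1 and Cyp2c40 were 0.30, -0.62 and -0.01 and none of the 3 was called. Mup9 was at -7.43 there (adjusted p = 0.00340) and Lpl at 0.84 (adjusted p = 0.366).

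Lists of tumour and injury genes moved up. Of 17 oncofetal and liver tumour markers 2 rose (H19 and Tspan8) and all 17 were positive (14 rose adjusted over the list alone), with a median log2 of 1.77, adjusted p = 3.03e-09 by camera and adjusted p = 0.352 with an estimated correlation. Afp, the fetal albumin relative used as a serum tumour marker, stood at 0.218 ± 0.0774 FPKM in Untreated and 29.4 ± 56.1 in DEN (log2 2.25, SE 0.84, adjusted p = 0.168), with 141 in DEN 4 and 0.343 in the lowest mouse. The tumour marker Gpc3 was at 1.16 (adjusted p = 0.122). Of 16 genes in the cholangiocyte and ductular list, drawn up for bile duct cells, 4 rose (13 adjusted over the list alone; median 0.92, adjusted p = 5.70e-10, adjusted p = 0.352 with an estimated correlation). They were Cdh1 (1.55, SE 0.39), Krt18 (1.00), Ddit4l (0.99) and Sox9 (0.85). Cdh1 also stands in the periportal hepatocyte list, so these rises need not come from duct cells. Of 17 p53 targets 3 rose, Bax (0.81, SE 0.20) besides Cdkn1a and Phlda3, and 7 rose adjusted over the list alone (median 0.43, adjusted p = 1.40e-06, adjusted p = 0.352 with an estimated correlation). The oncofetal list mean went from 1.80 to 1.23 without DEN 4.

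Genes induced by interferon, the alarm signal against viruses and stray nucleic acid, rose in 7 of 30 members (14 adjusted over the list alone; median 0.57, adjusted p = 3.25e-10; adjusted p = 0.365 with an estimated correlation). Oas1a went from 3.42 ± 0.921 to 11.4 ± 2.59 FPKM (log2 1.49, SE 0.26), Irf7 from 15 ± 1.83 to 40.8 ± 11.8 (1.34, SE 0.25), and Ifit1 had 1.25. Proliferation genes had a median of 0.46 over 18 members with 0 called (adjusted p = 0.00130, adjusted p = 0.609 with an estimated correlation). Mki67, the marker of cycling cells, was at 0.171 ± 0.0398 and 1.01 ± 1.13 FPKM. Extracellular matrix and stellate cell genes, the collagen makers of scarring liver, had a median of 0.48 over 27 members (3 rose adjusted over the list alone, adjusted p = 0.000771, adjusted p = 0.609 with an estimated correlation), with Col4a2 at 0.94. MHC class II genes (7 members, median 0.52, H2-Eb1 at 1.08), monocyte genes (11 members, 1 rose, Cd63; median 0.38) and the Kupffer cell list (14 members, median -0.32, Clec4f -0.77) each had adjusted p = 0.0186. The first 2 had adjusted p = 0.609 with an estimated correlation and Kupffer cells adjusted p = 0.63 with an estimated correlation. The unfolded protein response (23 members, median 0.26, Hspa5 0.84, adjusted p = 0.0187) and ribosomal protein genes (30 members, median 0.23, adjusted p = 0.000469) were also past the test. Both had adjusted p = 0.609 with an estimated correlation. NRF2 targets, the oxidant defence (25 members, 1 rose, Gsta1; median 0.36, adjusted p = 0.0186), and heat shock genes (13 members, median 0.23, adjusted p = 0.0386) had adjusted p = 0.63 with an estimated correlation. On leaving out DEN 4 list means went from 0.35 to 0.22 for proliferation, 0.56 to 0.31 for monocytes, 0.31 to 0.20 for the unfolded protein response and -0.28 to -0.18 for Kupffer cells. NRF2 targets went from 0.43 to 0.28 without Untreated 2 and heat shock genes from 0.23 to 0.15 without Untreated 3. Without the Untreated libraries with Xist reads the unfolded protein (adjusted p = 0.490 by camera) and monocyte lists (adjusted p = 0.0629 by camera) did not pass. The other lists named here passed there.

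Some lists of hepatocyte genes were lower. Of 19 pericentral genes, expressed around the central vein under Wnt signalling, 2 fell, Glul and Tbx3 (-1.10, SE 0.29), and 10 fell adjusted over the list alone (median -0.90, adjusted p = 4.96e-09; adjusted p = 0.352 with an estimated correlation). Bile acid genes (20 members, 1 fell; median -0.55, adjusted p = 4.70e-05) included the uptake carrier Slc10a1 (-1.60, SE 0.42), and AhR targets (7 members, median -0.40, adjusted p = 0.0131) included Ugt1a6a (-0.82). Both had adjusted p = 0.365 with an estimated correlation. Cyp1a2, which breaks down caffeine, was at 245 ± 92.2 and 182 ± 131 FPKM (-1.04, SE 0.60, adjusted p = 0.409), and its relative Cyp1a1 was under the filter at 0.30 ± 0.114 and 0.411 ± 0.271. CAR and PXR targets (23 members, median -0.49, Cyp2c37 -2.44, adjusted p = 0.0156) and hepatocyte identity genes (25 members, median -0.21, Hpd -0.96, adjusted p = 0.0186) had adjusted p = 0.609 with an estimated correlation. Cyp3a11, a PXR target, was at 253 ± 162 and 1064 ± 806 FPKM (1.79, adjusted p = 0.25). Fatty acid oxidation (25 members, median -0.28, Fabp1 -0.85, adjusted p = 0.0133; adjusted p = 0.63 with an estimated correlation) and cholesterol biosynthesis (25 members, median -0.17, adjusted p = 0.0476; adjusted p = 0.709 with an estimated correlation) had 0 called members. Much of this rests on DEN 4, without which list means went from -0.83 to -0.51 for pericentral, -0.59 to -0.28 for bile acid, -0.61 to -0.22 for CAR and PXR, -0.47 to -0.22 for AhR and -0.28 to -0.08 for fatty acid oxidation genes. Hepatocyte identity went from -0.20 to -0.09 without DEN 3 and cholesterol biosynthesis from -0.16 to 0.00 without DEN 1. Part also rests on the Untreated libraries with Xist reads. Without them CAR and PXR targets had a mean of -0.02 and did not pass (adjusted p = 0.174 by camera). Fatty acid oxidation genes had a mean of 0.008 there (adjusted p = 0.0375 by camera). Pericentral (mean -0.67), bile acid (-0.82), AhR and hepatocyte identity lists passed there as lower. The cholesterol list passed there too (adjusted p = 0.0322 by camera), but with 12 members positive, 13 negative and a mean of -0.08. Camera sets a list against the other genes, and the median of all genes was 0.12 there, so this is no clear fall.

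Of 24 female-biased liver genes, set by the growth hormone pattern, Sult3a1, Cyp2c40 and Atp6v0d2 (-1.13, SE 0.27) fell (14 adjusted over the list alone; median -1.85, adjusted p = 7.63e-08; adjusted p = 0.430 with an estimated correlation). Without the Xist libraries their median was 0.67 (adjusted p = 0.240), the opposite direction. Male-biased genes did not pass (23 members, Cib3 rose; median 0.26, adjusted p = 0.142), and without the Xist libraries their median was -1.04 (adjusted p = 1.11e-05; adjusted p = 0.559 with an estimated correlation). Of 18 clock genes, Nr1d1 and Nr1d2 (-1.61, SE 0.25, adjusted p = 0.000621) fell and Cry1 rose (1.47, SE 0.28, adjusted p = 0.00531), with 6 fallen and 1 risen adjusted over the list alone. The list had a median of -0.10 and a mean of -0.41 (adjusted p = 0.0439; adjusted p = 0.609 with an estimated correlation). Of 13 immediate early genes, switched on within minutes of a stimulus, 3 fell: Egr1 (-1.80, SE 0.39), Zfp36 (-1.49, SE 0.31) and Ier2 (-0.94, SE 0.20). Their median was -0.94 (adjusted p = 6.33e-05; adjusted p = 0.352 with an estimated correlation). Adenosine genes, the pathway whose receptors caffeine blocks (11 members; median -0.48, adjusted p = 0.0140; adjusted p = 0.365 with an estimated correlation), held a fall of Enpp1 (-0.48, SE 0.09). Adora1 was at 0.47, not called, and Adora2a (0.499 and 0.668 FPKM) and Adora2b (0.0195 and 0.0669) were under the filter.

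Other lists did not pass. Fatty acid synthesis had 2 called members, Pklr (-1.06) and Dgat2 (-0.68), both down, with a median of 0.05 and a mean of 0.03 (adjusted p = 0.755). MAPK output genes had 2 down, Spry4 (-0.73) and Egr1, with a median of 0.14 and a mean of -0.04 (adjusted p = 0.952). Sorafenib targets had 1 rise, Pdgfa (0.99; median 0.12, adjusted p = 0.181), with Kdr at -0.02, Pdgfrb 0.37 and Braf -0.06, and the periportal list had the rise of Cdh1 (median -0.06, adjusted p = 0.942). Members of the remaining lists were not called, with medians of -0.29 for gluconeogenesis, 0.17 for glycolysis and hypoxia, 0.43 for cytokines (Ccl2 1.14), 0.90 for neutrophils (S100a9 1.19) and -0.02 for B and plasma cells. The medians were -0.08 for endothelium, -0.12 for phosphodiesterases, -0.87 for blood (Hbb-bs -1.26), 0.30 for mitochondrially encoded genes and 0.24 for nuclear unspliced RNA. Median and mean differed in sign in the acute phase list (-0.04 and 0.07), T and NK cells (-0.01 and 0.07), the T cell checkpoint list (0.12 and -0.19) and ferroptosis (0.01 and -0.03). Too few members for the test had adipocytes (median 0.04), exocrine pancreas (-0.36), muscle (0.05) and mesothelium (0.57).

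For DEN against Untreated 260 of 12741 genes were called by limma, 128 up and 132 down, with 839 by edgeR and 1574 by DESeq2. Without the 3 Xist libraries 44 were called (58 by edgeR), and 7 of the 35 named called genes stayed: Gsta1, Mup9, Mup18, Nr1d1, Nr1d2, Cry1 and Phlda3. Cdkn1a was then at 2.91 (adjusted p = 0.108) and H19 at 5.09 (adjusted p = 0.135), with 2 Untreated mice left. Leaving out Untreated 3, 4 or 5 alone gave 146, 148 and 147 calls. On leaving out any 1 of the 11 libraries 18 of the 35 stayed, H19, Cdkn1a, Phlda3, Cib3, Lpl, Oas1a, Irf7 and Egr1 among them, while 17 were lost without at least 1. These are Ier2, Mup9, Mup18, Glul, Tspan8, Cd63, Sult3a1, Bax, Atp6v0d2, Slc10a1, Ifit1, Cyp2c40, Cyp46a1, Cyp2c69, Tbx3, Cdh1 and Krt18, with Glul lost without Untreated 4 or 5. On leaving out any 1 library the oncofetal, p53, cholangiocyte, interferon, matrix, pericentral, bile acid, female-biased, immediate early, adenosine and ribosomal lists passed each time, while each other list was lost without at least 1. With libraries numbered 3 and 4 as a batch 477 genes were called, among those libraries alone 540, and among the others 166.

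**Figure D2:**
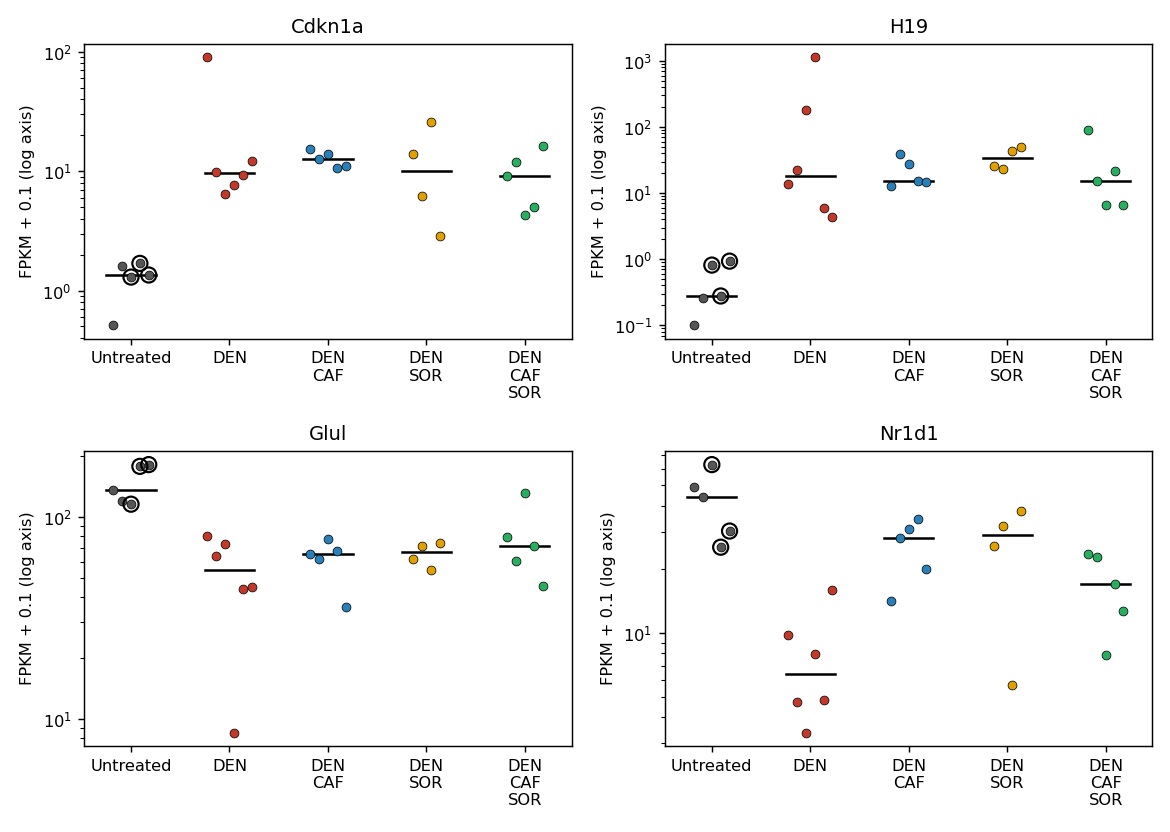
FPKM of Cdkn1a, H19, Glul and Nr1d1 in each mouse (log axis, FPKM + 0.1, bars are medians, rings mark Untreated libraries with Xist reads); from Untreated to DEN the means went from 1.19 to 22.4, 0.377 to 226, 146 to 52.4 and 42.2 to 7.66.

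With caffeine after the carcinogen 1 gene passed the test. Mterf2, a mitochondrial transcription regulator (ENSMUSG00000049038, chr10 84955297-84963891), rose from 1.32 ± 0.144 FPKM in DEN (n = 6) to 3.49 ± 1.27 in DEN_CAF (n = 5), log2 0.91 (SE 0.15, adjusted p = 0.0451), and stood at 2.30 ± 0.676 in Untreated. Nr1d1 was at 25.5 ± 8.32 FPKM against 7.66 ± 4.67 (log2 1.71, SE 0.41, adjusted p = 1.00) and Nr1d2 at 11.9 ± 2.50 against 5.88 ± 2.75 (0.98, SE 0.25), with Cry1 at -0.86 (SE 0.28). These 3 passed when adjusted over the list alone, and the clock list did not pass (adjusted p = 0.912). The labels give no hour of collection, so a shift of clock phase stays open for them. The tumour marker Afp was at 0.648 ± 0.201 FPKM against 29.4 ± 56.1 in DEN (-1.82), Gpc3 at -1.01, and Cdkn1a at 12.6 ± 1.93 (-0.07), none of them called. The DEN mean of Afp rests on DEN 4 (141 FPKM) and DEN 3 (32.1). The other DEN mice, at 0.343 to 1.52, overlapped the caffeine range of 0.397 to 0.866.

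Of 20 fatty acid synthesis genes, the SREBP-driven path from sugar to fat, 16 were lower with caffeine and 0 called (median -0.43, adjusted p = 5.74e-08; adjusted p = 0.164 with an estimated correlation). Thrsp, an activator of this path, was at 22.7 ± 7.21 against 58.8 ± 34.2 FPKM (-1.19, SE 0.46) and the desaturase Scd1 at 350 ± 229 against 615 ± 218 (-0.98, SE 0.39). The mean of this list per mouse was 0.40 lower (log2; exact permutation p = 0.0130, adjusted 0.195), and it passed on leaving out any 1 library. Neutrophil genes were lower (median -0.86, S100a9 -1.30, S100a8 -1.23, adjusted p = 0.00350; adjusted p = 0.623 with an estimated correlation), but the exact permutation p of their mean was 0.296, adjusted 0.816, and the call was lost without DEN 3 or DEN 4, with the mean going from -0.81 to -0.28 without DEN 4. Oncofetal genes (-0.49, adjusted p = 0.0387), endothelial genes (-0.09, adjusted p = 0.0274) and ribosomal genes (-0.09, adjusted p = 0.00353) were lower and pericentral genes higher (0.36, adjusted p = 0.000345), with 18 of 19 positive. Each of these 4 had adjusted p = 0.976 with an estimated correlation. Each was also lost without at least 1 library. Leaving out DEN 4 took the mean from -0.44 to 0.13 for oncofetal, 0.38 to 0.05 for pericentral and -0.08 to -0.02 for ribosomal genes, and leaving out DEN 2 took that of endothelium from -0.12 to -0.07. For endothelium the exact permutation p was 0.292, adjusted 0.816.

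For DEN_CAF against DEN 1 gene was called by limma, 0 by edgeR and 10 by DESeq2, and 358 genes had an unadjusted p under 0.05 where 637 would be expected by chance. Mterf2 was lost on leaving out any DEN library or DEN_CAF 2, 3 or 5, and with libraries numbered 3 and 4 as a batch (adjusted p = 0.0563; 9.98e-05 to 0.940 over all settings). Among those libraries alone, and among the others, 0 genes were called. The list count of 6 moved to 3, 10 and 12 without DEN 4, 5 and 6. Expression of Adora1 (0.51), Cyp1a2 (0.86), Cyp3a11 (0.31), Glul (0.45), Mki67 (-0.05), Kdr (-0.27), Pdgfrb (0.04) and Braf (-0.10) was not called, and Cyp1a1 stood at 0.607 ± 0.132 FPKM.

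With sorafenib, a kinase inhibitor used in liver cancer, endothelial genes were lower than in DEN. All 19 tested members were negative, 0 called among all genes and 5 fallen adjusted over the list alone (median -0.56, adjusted p = 6.97e-11; adjusted p = 0.515 with an estimated correlation). Pecam1, the junction protein of vessel walls, was at 1.14 ± 0.477 FPKM (n = 4) against 2.80 ± 1.25 (n = 6), log2 -0.80 (SE 0.20). Tie1 had -0.76 (SE 0.20) and the VEGF receptor Kdr 1.56 ± 0.862 against 3.42 ± 0.824 (-0.83, SE 0.23, adjusted p = 0.473). The mean of the list per mouse was 0.54 lower (log2, SE 0.21; exact permutation p = 0.0429, adjusted 0.357). By mouse it was -1.06 in DEN_SOR 1 and -0.69 in DEN_SOR 4, which has 34.8% mitochondrial reads. DEN_SOR 2 and 3, at -0.09 and 0.04, lay within the DEN range of -0.19 to 0.38. The list passed on leaving out any 1 library, with a difference of -0.34 without DEN_SOR 1. Without libraries above 20% mitochondrial reads the difference was -0.49 (SE 0.25, bounds of 2 SE -0.995 to 0.0133).

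Fatty acid synthesis genes were lower in 19 of 20 members (median -0.45, adjusted p = 1.30e-05; adjusted p = 0.515 with an estimated correlation), with Scd1 at 231 ± 78.8 against 615 ± 218 FPKM (-1.42, SE 0.42) and Fads1 at -0.61. The exact permutation p of their mean was 0.0190, adjusted 0.214. Clock genes were higher (median 0.61, adjusted p = 0.00181, adjusted p = 0.515 with an estimated correlation). Adjusted over the list alone 9 rose and 3 fell, as with Nr1d2 (14.9 ± 5.44 against 5.88 ± 2.75 FPKM, 1.23, SE 0.26), Nr1d1 (1.49) and Npas2 (-0.82). Dbp minus Arntl, a score of clock phase (log2), was 4.81, 5.12, -0.97 and 5.36 in DEN_SOR 1 to 4. In DEN it ran from -1.72 to 0.03. The labels give no hour of collection, so that hour and a response to sorafenib cannot be told apart. Female-biased genes were higher (median 0.97, Cyp4a10 2.91, Sult1e1 2.54, adjusted p = 4.62e-07), as were gluconeogenesis genes, the fasting output of glucose (0.46, Slc37a4 1.15, adjusted p = 0.00280), and immediate early genes (0.40, Egr1 1.07, adjusted p = 0.00181). These 3 lists were at adjusted p = 0.843 with an estimated correlation. Pericentral (0.42, adjusted p = 0.00477), CAR and PXR (0.33, adjusted p = 0.0117), interferon (0.25, adjusted p = 0.000385), MHC class II (0.33, adjusted p = 0.0460) and mitochondrially encoded genes (0.38, adjusted p = 0.0212) were higher too, but each was lost without at least 1 library. They had adjusted p = 0.843 with an estimated correlation. The mean of mitochondrially encoded genes went from 0.49 to -0.01 without DEN_SOR 4, so it is carried by that library. Without DEN 4 means went from 0.39 to 0.07 for pericentral, 0.39 to 0.00 for CAR and PXR and 0.45 to 0.21 for gluconeogenesis genes, and the last list was lost. Those of interferon genes went from 0.24 to 0.12 without DEN_SOR 2 and of MHC class II from 0.31 to 0.15 without DEN_SOR 3. The mean of the female-biased list was 1.32 higher with all mice and 0.76 without DEN_SOR 1. That of immediate early genes was 0.37 with all mice, 0.20 without DEN_SOR 3 and 0.60 without DEN_SOR 4.

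No single gene was called by limma (smallest adjusted p = 0.252): 0 genes, with 789 at an unadjusted p under 0.05, 0 by edgeR and 23 by DESeq2. The smallest p among higher genes were those of Ppargc1b (0.70), Nr1d2 and Sorbs3 (1.51), and among lower ones of Inhba (-1.06), Fam167b (-1.44) and Nelfa (-0.56). Without DEN 1 the limma count was 11 and without DEN_SOR 3 it was 1. Among libraries not numbered 3 or 4 it was 13 and among those numbered so 0, with 2 sorafenib mice in each. Sorafenib targets did not pass (median -0.06, adjusted p = 0.607), with Pdgfrb at -0.07 and Braf at -0.08. Afp (-1.05), Gpc3 (-0.68), Cdkn1a (-0.49), Glul (0.58), Mki67 (-0.07), Cyp1a2 (0.52), Cyp3a11 (0.03) and Adora1 (0.20) were not called, and Cyp1a1 stood at 0.970 ± 0.481 FPKM. B and plasma cell genes did not pass (adjusted p = 0.113), with 2 risen, Ighg1 (1.82) among them, and 1 fallen adjusted over the list alone.

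**Figure D3:**
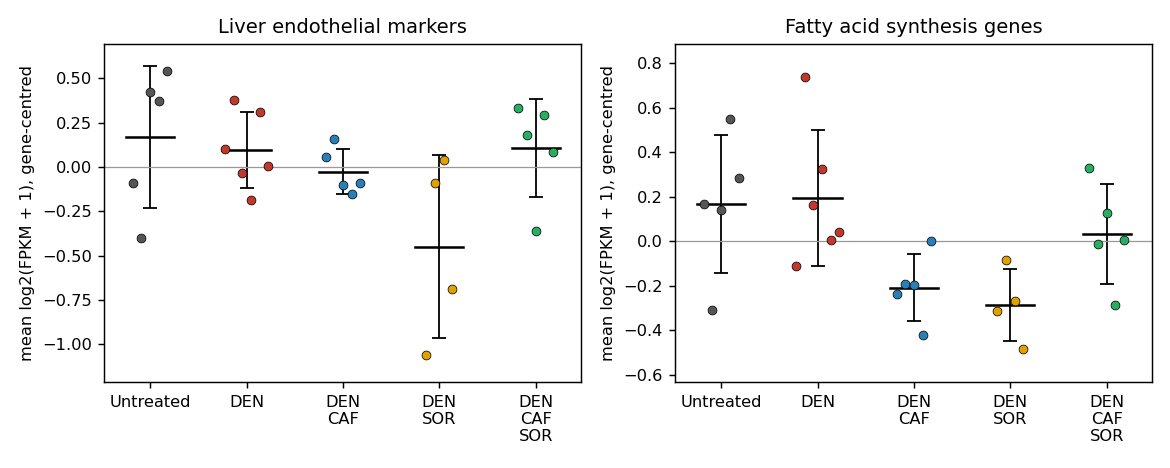
Mean of gene-centred log2(FPKM + 1) per mouse over the endothelial and the fatty acid synthesis genes (bars are mean and SD); DEN_SOR minus DEN is -0.54 for endothelium, and DEN_CAF minus DEN -0.40 for fatty acid synthesis.

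With both drugs, Kupffer cell genes, those of the resident liver macrophages, were higher than in DEN in 14 of 14 members (median 0.40, adjusted p = 0.00262, adjusted p = 0.812 with an estimated correlation), for example Fcna (0.63), Clec4f (0.55) and Timd4 (0.49). Their mean went from 0.36 to 0.14 without DEN_CAF_SOR 1, where the call was lost. Bile acid genes were higher (0.23, adjusted p = 0.0467, adjusted p = 0.849 with an estimated correlation), with the synthesis enzyme Cyp7a1 at 1.47 (SE 0.66) and the carrier Slc10a1 at 1.01 (SE 0.42). Pericentral genes were higher (0.21, adjusted p = 0.00262, adjusted p = 0.812 with an estimated correlation), with Glul at 77.7 ± 32.6 FPKM (n = 5) against 52.4 ± 26 (0.74). Oncofetal genes were lower (-0.63, adjusted p = 0.00262), with Afp at 1.46 ± 1.45 FPKM (-1.41) and Gpc3 at -0.63, and p53 targets were lower (-0.21, adjusted p = 0.00262), with Cdkn1a at 9.23 ± 4.97 (-0.62). The last 2 lists were at adjusted p = 0.812 with an estimated correlation. Leaving out DEN 4 took the mean from 0.31 to 0.01 for bile acid, 0.34 to 0.02 for pericentral and -0.61 to -0.04 for oncofetal genes, and leaving out DEN 1 that of p53 targets from -0.26 to -0.14.

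Fatty acid synthesis (-0.22, Fads2 -0.69, adjusted p = 0.0386), neutrophil (-1.01, adjusted p = 0.0464) and unfolded protein genes (-0.27, adjusted p = 0.0204) were lower, and AhR targets (0.22, adjusted p = 0.0253) and immediate early genes (0.33, Egr1 0.97, adjusted p = 0.00656) higher. These 5 had adjusted p = 0.812 with an estimated correlation. CAR and PXR targets (0.60, Por 0.91, adjusted p = 0.0182), male-biased genes (0.43, adjusted p = 0.0182), ferroptosis genes (0.13, adjusted p = 0.0386) and ribosomal genes (0.09, adjusted p = 0.0283) were higher, and interferon genes lower (-0.16, adjusted p = 0.0182), at adjusted p = 0.849 with an estimated correlation. With DEN 4 left out the means went from -0.68 to -0.15 for neutrophil, -0.17 to -0.05 for unfolded protein, 0.37 to 0.12 for AhR, 0.44 to 0.05 for CAR and PXR and 0.14 to 0.06 for ferroptosis genes. Fatty acid synthesis went from -0.16 to -0.05 without DEN 2 and male-biased genes from 0.56 to 0.17 without DEN 3. Dropping DEN_CAF_SOR 3 took interferon from -0.15 to 0.01 and ribosomal genes from 0.09 to -0.01. The clock list did not pass (adjusted p = 0.0875), with Nr1d2 at 1.01.

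By limma 0 genes were called, with 346 at an unadjusted p under 0.05, 0 by edgeR and 0 by DESeq2. Smallest p had Nr1d2, Fn3k (0.54) and Mterf2 (0.51) among higher genes and Helz2 (-0.66), Gas2l1 (-0.41) and Med24 (-0.36) among lower ones, each at adjusted p = 1.00. With libraries numbered 3 and 4 as a batch 0 genes were called, among those alone 6 and among the others 0. Each of the 15 lists was lost without at least 1 library: Kupffer cells without DEN_CAF_SOR 1, pericentral genes without DEN 4, p53 targets without DEN 1. The number of lists was 7 without DEN 4 or DEN_CAF_SOR 5, and 8 without DEN 3, DEN_CAF_SOR 2 or DEN_CAF_SOR 4. Mki67 (-0.08), Cyp1a2 (0.88), Cyp3a11 (0.74), Adora1 (0.13), Kdr (-0.18), Pdgfrb (-0.06) and Braf (-0.01) were not called, and Cyp1a1 stood at 0.725 ± 0.224 FPKM.

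Endothelial genes were higher with both drugs than with sorafenib alone, in 19 of 19 members (median 0.56, adjusted p = 9.56e-13; adjusted p = 0.673 with an estimated correlation). Kdr was at 2.92 ± 0.854 FPKM (n = 5) against 1.56 ± 0.862 (n = 4; 0.65), Pecam1 at 2.10 ± 0.590 against 1.14 ± 0.477 (0.54), and Plvap, of fenestrated vessels, at 0.84. The exact permutation p of the list mean, 0.56 higher, was 0.0794, adjusted 0.446. The difference rests on DEN_SOR 1 (-1.06) and DEN_SOR 4 (-0.69; 34.8% mitochondrial reads), and without DEN_SOR 1 it was 0.35. Fatty acid synthesis genes were higher (0.34, adjusted p = 0.00759, adjusted p = 0.782 with an estimated correlation), with Scd1 at 671 ± 331 against 231 ± 78.8 FPKM (1.47, SE 0.44). Interferon genes were lower (-0.38, Ifit1 -0.91, Oasl2 -0.61, adjusted p = 7.19e-11), as were B and plasma cell genes (-0.71, adjusted p = 0.00534), where Ighg1 (-2.09), Igkc (-1.74) and Jchain (-1.06) passed adjusted over the list alone. Both lists had adjusted p = 0.782 with an estimated correlation.

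Female-biased genes were lower (-1.22, adjusted p = 1.09e-07) and male-biased genes higher (0.90, adjusted p = 1.10e-05), and oncofetal (-0.56, adjusted p = 0.00139), cholangiocyte (-0.40, adjusted p = 0.000736) and unfolded protein genes (-0.14, adjusted p = 0.0116) were lower, at adjusted p = 0.782 with an estimated correlation. Acute phase (-0.24, adjusted p = 0.0279) and mitochondrially encoded genes (-0.36, adjusted p = 0.0215) were lower and matrix (0.19, adjusted p = 0.0279) and ribosomal genes (0.18, adjusted p = 0.00104) higher, at adjusted p = 0.941 with an estimated correlation. Without DEN_SOR 4 the mean of mitochondrially encoded genes turned from -0.40 to 0.11, and matrix went from 0.22 to 0.02 and ribosomal genes from 0.16 to 0.05. Without DEN_SOR 1 acute phase genes went from -0.34 to -0.02, female-biased from -1.24 to -0.68, male-biased from 1.2 to 0.71 and B and plasma cell genes from -0.69 to -0.39. Without DEN_SOR 3 cholangiocyte genes went from -0.32 to -0.14 and unfolded protein genes from -0.18 to -0.11, and without DEN_CAF_SOR 3 interferon genes from -0.39 to -0.23. Oncofetal, female-biased, interferon, B and plasma cell and endothelial lists passed on leaving out any 1 library, each of the others was lost without at least 1. Single genes numbered 0 by limma, with 432 at an unadjusted p under 0.05, 0 by edgeR and 0 by DESeq2. Smallest p had Tbc1d7 (0.45), Esam (0.84), Rpp30 (0.39), Atg14 (-0.60), Ptcd1 (-0.46) and Cd320 (-0.55), at adjusted p = 1.00. Within either set of library numbers, and with the batch, 0 genes were called.

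Sorafenib added to caffeine went with higher fatty acid synthesis genes (median 0.25, adjusted p = 0.0142, adjusted p = 0.825 with an estimated correlation). Thrsp was at 96.2 ± 97.3 FPKM (n = 5) against 22.7 ± 7.21 (n = 5), log2 1.66 (SE 0.48), which passed adjusted over the list alone, and Scd1 at 1.03. Kupffer cell genes were higher in 14 of 14 members (0.26, adjusted p = 0.00360), ribosomal genes in 30 of 30 (0.17, adjusted p = 6.36e-08), and p53 targets lower (-0.26, adjusted p = 0.0151). These 3 were at adjusted p = 0.825 with an estimated correlation. Hepatocyte identity (0.09), male-biased (0.38), gluconeogenesis (0.36), cytokine (0.19), matrix (0.12), endothelial (0.14) and blood genes (0.56) were higher and interferon genes lower (-0.18), each at adjusted p = 0.0417. These 8 had adjusted p = 0.825 with an estimated correlation. On leaving out any 1 library fatty acid synthesis and ribosomal genes passed each time and the other 10 did not. Means went from 0.13 to -0.04 for matrix, 0.15 to -0.01 for cytokines and 0.13 to 0.08 for endothelium without DEN_CAF_SOR 1. Dropping DEN_CAF_SOR 3 took interferon from -0.18 to -0.01, ribosomal genes from 0.17 to 0.08 and p53 targets from -0.23 to -0.13. Those of hepatocyte identity and gluconeogenesis went from 0.13 to 0.04 and 0.28 to 0.08 without DEN_CAF 3, and that of male-biased genes from 0.43 to 0.10 without DEN_CAF 1. Exact permutation p of the list mean was 0.357 for endothelium (0.13, SE 0.20), 0.603 for matrix and 0.405 for Kupffer cells, where the mean went from 0.29 to 0.07 without DEN_CAF_SOR 1. Single genes numbered 0 by limma, with 376 at an unadjusted p under 0.05, 0 by edgeR and 0 by DESeq2. Smallest p had Thrsp, the pseudogene Rpl36a-ps1 (0.77), Rilpl2 (0.37), Wdr81 (-0.71), Tnrc18 (-0.33) and Zbtb7b (-0.43), at adjusted p = 1.00. Within either set of library numbers, and with the batch, 0 genes were called.

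The interaction asks whether the caffeine difference depends on sorafenib. Fatty acid synthesis genes, lower with each drug alone, had a positive interaction (median 0.70, adjusted p = 1.21e-07; adjusted p = 0.219 with an estimated correlation), with Scd1 at 2.45 (SE 0.59), which passed adjusted over the list alone. Endothelial genes were positive in 19 of 19 members (0.69, adjusted p = 2.25e-11; adjusted p = 0.460 with an estimated correlation), for example Plvap (1.25), Kdr (0.92) and Pecam1 (0.90). The stress kinase inhibitor Trib3 was at 16.7 ± 4.59 FPKM with caffeine, 16.0 ± 4.73 with sorafenib, 9.27 ± 1.14 with both and 6.72 ± 2.63 in DEN (interaction -1.92, SE 0.37, adjusted p = 0.184). Atg14, which starts autophagosomes, had -1.02 (SE 0.19, adjusted p = 0.184).

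Male-biased (0.88, adjusted p = 0.00455), matrix (0.41, adjusted p = 0.00497) and ribosomal genes (0.26, adjusted p = 1.23e-05) also had positive medians, and female-biased genes a negative one (-1.36, adjusted p = 3.08e-05), at adjusted p = 0.903 with an estimated correlation. Pericentral (-0.30, adjusted p = 0.0168), interferon (-0.41, adjusted p = 1.15e-05), cholangiocyte (-0.49, adjusted p = 0.00641) and mitochondrially encoded genes (-0.65, adjusted p = 0.00497) were negative, at adjusted p = 0.903 with an estimated correlation. By limma 0 genes were called, with 506 at an unadjusted p under 0.05, 0 by edgeR and 11 by DESeq2. Female-biased, fatty acid synthesis, interferon, endothelial and ribosomal lists passed on leaving out any 1 library, the other 5 were lost without at least 1. Means moved from -1.68 to -1.12 for female-biased and 1.07 to 0.58 for male-biased genes without DEN_SOR 1, and from -0.42 to -0.25 for interferon genes without DEN_CAF_SOR 3. On leaving out DEN_SOR 4 they moved from 0.24 to 0.13 for ribosomal, 0.33 to 0.13 for matrix and -0.81 to -0.31 for mitochondrially encoded genes. Pericentral genes moved from -0.43 to -0.10 without DEN 4 and cholangiocyte genes from -0.42 to -0.25 without DEN_SOR 3. Slc44a1 (0.77), Inhba (1.21) and Mterf2 (-0.98) were the other genes of smallest p. Without DEN 1 the count was 1. Within either set of library numbers, and with the batch, 0 genes were called.

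The 3 treatments shared 0 called genes against DEN. Fold changes of 12741 genes correlated at 0.517 between caffeine and sorafenib, 0.493 between caffeine and both, and 0.482 between sorafenib and both, while unchanged simulated groups that share the DEN mice gave 0.417, 0.412 and 0.408. With the DEN mice split so that no mouse enters both sides the values were -0.00538, -0.129 and 0.00286. Against the DEN effect the correlations were -0.394, -0.181 and -0.441 for caffeine, sorafenib and both, with simulated values of -0.418, -0.377 and -0.430 and split values of 0.00150, 0.0626 and -0.0346. Across all genes, neither a shared drug response nor a return to the untreated level is thus separable from the shared DEN mice. Single genes such as Nr1d1, Glul or H19 were not tested for a return in this way.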

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

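The tests weighed here were chosen only after the result was seen, except those of mitochondrial share, GC content and gene length for the libraries numbered 3 and 4 and the interaction test.

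A mouse far from the rest of its group was looked for in 105 group tests. Some genes entered for their change in these same mice, so the chance value of 1 in 20, or 5, is only rough. In 10 tests a mouse stood apart. In Untreated these were Gpc3 at 0.656 FPKM in mouse 5 (others 0.0661 to 0.186), Cdkn1a at 0.412 in mouse 1 (others 1.2 to 1.59) and Cyp1a2 at 408 in mouse 1 (others 187 to 226). In DEN the mitochondrial share was 33.4% in mouse 3 (others 6.74% to 9.58%). DEN 1 had Cdkn1a at 89.7 FPKM (others 6.32 to 12.1) and Cib3 at 61.0 (others 12.0 to 20.7). DEN 4 had Glul at 8.43 FPKM (others 44.0 to 79.95), S100a11 at 255 (others 18.9 to 39.1), Ifi27l2b at 347 (others 29.7 to 67.1) and Cyp46a1 at 1.25 (others 22.9 to 39.2).

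The caffeine difference differed between mice with and without sorafenib in 10 lists by the interaction test (median log2 difference). It was 0.70 for fatty acid synthesis, 0.69 for endothelium, 0.88 for male-biased genes, 0.41 for matrix and stellate cell genes and 0.26 for ribosomal proteins. It was -0.30 for pericentral genes, -1.36 for female-biased genes, -0.41 for interferon genes, -0.49 for cholangiocyte genes and -0.65 for mitochondrially encoded genes. With a correlation estimated per list 0 of the 10 passed.

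Xist, which no comparison of the report tests for sex, had 22879, 29770 and 13370 reads in Untreated 3, 4 and 5, against 0 to 21 in the other 22 libraries, and female-biased liver genes were lower in DEN than in Untreated. Whether libraries were swapped between Untreated and a treated group cannot be decided from Xist. The highest Xist count in the 20 carcinogen-treated libraries was 21, but a library exchanged for 1 of the 3 need not carry Xist reads. That the 3 libraries come from female livers is a candidate explanation for the lower list: without them the mean of the list was 0.918 (SE 0.678) in place of -1.70 (SE 0.795). Carcinogen treatment lowering such genes in male livers stays open, with 2 Untreated mice left. Without the 3 libraries 5 members were negative and 19 positive, so the list as a whole was not lower there. Bounds of 2 SE around the mean ran from -0.438 to 2.27. With all carcinogen-treated livers as 1 set the median was then 1.05 (adjusted p = 0.00938 by camera, adjusted p = 0.722 with an estimated correlation).

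Nr1d1 and Nr1d2 were lower and Cry1 higher in DEN than in Untreated, and the labels give no hour of collection. Libraries rich in mitochondrial reads are argued against, since 3 of 3 genes were called without libraries above 20% (-2.24, -1.48 and 1.48). A shift of clock phase stays open. With Dbp minus Arntl as covariate 74% of the change was left (median of the 3), but 1 linear score cannot take out a daily cycle. The calls of Nr1d1 (-1.88, adjusted p = 0.0385) and Nr1d2 (-1.19, adjusted p = 0.0156) held, while that of Cry1 ended as its fold went from 1.47 (SE 0.28) to 0.90 (SE 0.24). A response to the carcinogen and the hour of collection stay open: the other 3 carcinogen-treated groups had 40.6% of the DEN difference (median of the 3 genes).

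Libraries numbered 3 and 4 differed from the others in a fit over all carcinogen-treated groups. No group was tested alone, and the differences correlated between groups at 0.195 to 0.614. The fit put 4122 genes past the test (821 up, 3301 down, 8 libraries against 12, limma). Of 100 random choices of 2 libraries per group the real one was the 1 with as many, the highest other having 1477, but these numbers were picked because they stood apart among 10 pairs, so chance is not excluded by this. As the whole cause, mitochondrial reads taking a share of the total are argued against: 3604 genes passed without mitochondrial genes in totals and tests. This does not test other things that may go with a high mitochondrial share, which stay open. Gene length is argued against too (rho -0.0416). GC content stays open (rho 0.267, per group 0.123 to 0.292), as does more tumour tissue in the sampled pieces, with oncofetal genes above 0 in 2 of 4 groups, beyond error in DEN alone (log2 2.91, SE 0.62, with DEN 4 in it; DEN_CAF -0.21, SE 0.15; DEN_SOR -0.11, SE 0.30; DEN_CAF_SOR 0.09, SE 0.58). The labels name no batch or day, and no biological explanation from the design was tested, since each group holds both numbers.

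For DEN against Untreated 1 of 100 splits of the same mice, the real one, gave as many genes (260, highest other 8). A random grouping of these mice is thus argued against for the gene count. The splits cannot tell the carcinogen from sex, since all 3 libraries with Xist reads are Untreated, and 44 genes were called without them. As many lists came from 5 splits (24, highest other 26), so chance is not excluded for the list count. In the drug comparisons chance is not excluded for any count above 0, and a real count of 0 genes cannot be tested this way, since every split gives as many. For DEN_CAF against DEN 7 of 100 splits gave as many genes (1, highest other 1582) and 96 as many lists (6, highest other 25). For DEN_SOR against DEN it was 100 for genes (0, highest other 2680) and 72 for lists (11, highest other 23), and for DEN_CAF_SOR against DEN 100 (0, highest other 1) and 51 (15, highest other 28). For DEN_CAF_SOR against DEN_SOR it was 100 (0, highest other 22) and 19 (13, highest other 17), and against DEN_CAF 100 (0, highest other 0) and 34 (12, highest other 22). For the interaction it was 100 (0, highest other 1) and 74 (10, highest other 22). In each comparison all 99 other splits gave lists past the test. The median per split ran from 9 lists for DEN_CAF_SOR against DEN_CAF to 16 for DEN against Untreated. The splits with 1582 and 2680 genes put libraries numbered 3 and 4 on the same side, which points to the structure of the samples described above; with those numbers as a batch DEN_CAF and DEN_SOR against DEN each had 0 genes.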

How the results depend on the processing

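Settings with genes absent from a table as 0, with a covariate, without Xist or mitochondria-rich libraries, by library number, with edgeR or with DESeq2 were chosen after the data were seen; the others were set beforehand. Where a value moved, the cause was not tested, apart from fewer libraries or genes by construction.

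For DEN against Untreated (260 genes, 128 up and 132 down) the count was 1054 with library weights (638 up, 416 down), 568 with the mitochondrial share as covariate (354, 214) and 117 with Dbp minus Arntl (32, 85). It was 477 with numbers 3 and 4 as a batch (240, 237), 166 with numbers 1, 2, 5 and 6 only (114, 52), 540 with numbers 3 and 4 only (147, 393) and 124 with the compared groups only (73, 51). It was 44 without the Xist libraries, 839 with edgeR, 58 with edgeR without the Xist libraries and 1574 with DESeq2. Leaving out 1 library gave 146 (Untreated 3) to 318 (DEN 1), with 147 and 148 without Untreated 5 and 4. Cyp2c69 (Cyp2c69: DEN against Untreated) reversed from -3.81 to 0.30 without the Xist libraries, and to 5.91 with edgeR without them.

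For DEN_CAF against DEN (1 gene, Mterf2, adjusted p from 9.98e-05 to 0.940 over all settings) limma called 0 under TPM scaling, without libraries above 20% mitochondrial reads, with either covariate, with the number batch, within either set of numbers and with the compared groups only. edgeR called 0 with and without the Xist libraries, library weights gave 6 and DESeq2 10, and leaving out 1 library gave 0 to 1. For DEN_SOR against DEN (0 genes by limma) it was 1 without a filter, 6 with library weights, 13 with numbers 1, 2, 5 and 6 only, 23 with DESeq2 and 0 to 11 leaving out 1 library (11 without DEN 1, 1 without DEN_SOR 3). For DEN_CAF_SOR the limma count of 0 was 6 against DEN with numbers 3 and 4 only, and 1 against DEN_SOR and 1 against DEN_CAF without a filter. Leaving out 1 library gave 0 in each of these 3. For the interaction it was 2 without a filter, 11 with DESeq2 and 0 to 1 leaving out 1 library (1 without DEN 1).

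With an estimated correlation 0 lists passed in any of the 7 comparisons. For DEN_SOR against DEN 17 lists passed with Dbp minus Arntl as covariate, against 11. For DEN_CAF_SOR against DEN 8 passed without libraries above 20% mitochondrial reads, against 15, and for DEN_CAF_SOR against DEN_CAF 5 under median-ratio scaling, against 12. Leaving out 1 library gave 17 to 25 lists for DEN against Untreated, 3 to 12 for DEN_CAF, 10 to 15 for DEN_SOR and 7 to 17 for DEN_CAF_SOR against DEN, 10 to 14 against DEN_SOR, 8 to 12 against DEN_CAF and 7 to 14 for the interaction. Counts moved over 1.5 times without DEN 4, 5 or 6 for caffeine (3, 10 and 12 lists, against 6). For both drugs against DEN they did without DEN 3 (8), DEN 4 (7) and DEN_CAF_SOR 2 (8), 4 (8) and 5 (7). With the DEN libraries split, correlations between treatments were -0.00538, -0.129 and 0.00286 and with the DEN effect 0.0015, 0.0626 and -0.0346.

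Whether replicate numbers pair mice across groups is not settled. Same-number pairs correlated at a mean of 0.120, against -0.0262 for other pairs, with 25 of 46 above 0.1 and the lowest at -0.282. Of 25 libraries 8 correlated best with their own number. With the replicate block DEN_CAF against DEN had 0 genes and 12 lists, and no other count moved over 1.5 times. Of the named called genes of DEN against Untreated, settings fixed beforehand left 227 of their results past the test and 53 not, those chosen later 256 and 127 with 2 reversed, and leaving out 1 library 276 and 109. The self-test recovered 8.96% of 1.5-fold changes at these depths, so small changes can be missed.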

Other observations

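The tests in this part were chosen only after the data were seen. As 1 set, the 20 carcinogen-treated livers, with or without drugs, differed from the 5 Untreated ones in 664 genes by limma (402 up, 262 down), and in 56 without the Xist libraries (29 up, 27 down), 50 of them in both. In 132 genes the 2 sets did not overlap (86 higher, 46 lower), where a random grouping of the libraries gives 0.48 genes (0.00376% each). That value does not allow for sex, since the libraries with Xist reads are all Untreated, so the 132 cannot be credited to the carcinogen alone. Genes without overlap were not counted again without those libraries. Mmp7, a matrix protease of ductular cells, rose from 0.249 ± 0.127 to 16.1 ± 19.7 FPKM (log2 3.11, SE 0.55, adjusted p = 0.00160) and Spp1, the secreted osteopontin, from 8.39 ± 1.90 to 60.4 ± 44.3 (2.45, SE 0.44, adjusted p = 0.00164). Without the Xist libraries these 2 were at 2.97 (adjusted p = 0.146) and 2.34 (adjusted p = 0.144). Anxa13 (log2 2.15, adjusted p = 9.97e-05), Oas1g (1.75, adjusted p = 2.61e-06) and Tmem43 (1.15, adjusted p = 2.1e-05) rose and stayed called without them. Rfx4 went from 3.63 to 0.332 FPKM (-1.74, adjusted p = 1.33e-07), Nxpe2 from 4.32 to 0.905 (-1.48, adjusted p = 1.33e-07), Gna14, a G protein, from 2.37 to 0.484 (-1.16, adjusted p = 5.14e-06) and Camk1d, a calcium-driven kinase, from 6.50 to 2.18 (-1.26, adjusted p = 3.03e-07). These 4 stayed called without the Xist libraries too. Lifr, the receptor of leukemia inhibitory factor, fell from 37.0 to 15.3 FPKM (-1.23, adjusted p = 0.00134), and was at -1.38 without them (adjusted p = 0.0629).

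Among livers without Xist reads (6 DEN, 2 Untreated), 44 genes were called by limma, 37 of them shared with the 260. Cyp2a4, a steroid hydroxylase with a close copy in Cyp2a5, was at 5.80 (SE 1.12, adjusted p = 0.0193) against 0.74 with all libraries, and Cyp2b9 at 4.62 (SE 0.93, adjusted p = 0.0277) against -0.10. The tubulin genes Tubb2a (3.32) and Tubb4b (1.79) were higher and Sult5a1 (-2.73) lower. With 2 Untreated mice these values rest on few animals.

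In DEN 4 Afp was at 141 FPKM, H19 at 1130, Gpc3 at 13.7 and Lcn2 at 1981. Its Ddx3y count was 132 reads and its Eif2s3y count 1004, while the other carcinogen-treated libraries had 914 to 1689 reads of Ddx3y. In libraries numbered 3 and 4 of the carcinogen-treated groups, 13 of 13 mitochondrially encoded genes had higher values (median log2 1.47), which restates the mitochondrial share by which these libraries stand apart, and 15 of 25 fatty acid oxidation genes fell (-0.64, adjusted p = 0.0105; adjusted p = 0.909 with an estimated correlation). Single genes there were mt-Rnr1 (1.90), Ugt1a1 (-2.48), Rnf149 (-2.07), Dhrs1 (-1.53) and Arf6 (-1.50).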
